A study of Mus musculus with 2 samples.

How the data were processed

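Counts were taken as deposited, as whole-number UMI counts per gene and barcode, 1 table for the MOCK library and 1 for the NAV library. Per the submitters' processing notes, fastp, STARsolo 2.7.10a, Cell Ranger and the mm10 build were used, and the notes give no role or order for them. Per the labels the CD45+ cells of the tumours of each group were pooled into 1 BD Rhapsody library. The tables held 31253 genes, and no barcode had fewer than 500 UMIs, so a minimum had been applied before deposit. Genes were matched by Ensembl identifier to GENCODE vM21 on GRCm38, the assembly also called mm10, which 31107 of the identifiers were in. The gene symbols held 43 duplicates, and 5 symbols of the marker and gene lists were not in the tables: Mb21d1, Mx1, Tcrg-C1, Tcrg-C2 and Tmem173. Mb21d1 and Tmem173 are older symbols of Cgas and Sting1, which the cGAS-STING list also holds and which were read. The tables hold Tcrg-C1 and Tcrg-C2 as Trgc1 and Trgc2, which were not used as markers.

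Barcodes with at least 500 UMIs, 200 genes and under 20% mitochondrial UMIs were kept, which left 10770 MOCK and 10441 NAV barcodes and removed 93 and 24. Median mitochondrial shares were 3.29% and 3.01%. Doublet scores were computed with Scrublet per library. Its automatic threshold marked under 0.5% of barcodes and had not worked, so after the data were seen barcodes with a score above 0.25 (178 MOCK and 184 NAV, 1.65% and 1.76%) and clusters with a median score above 0.10 (514 and 419 barcodes) were removed. The cells analysed numbered 10078 and 9838, with medians of 3698 and 1992 UMIs and 1686 and 1104 genes.

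Both libraries were clustered together, without batch correction. Counts were scaled to 10000 per cell and logged, genes in at least 3 cells were kept, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 were used. Lymphoid and mononuclear phagocyte clusters were clustered again, and alpha-beta T cells once more at resolution 2.0. Clusters were named from marker lists of 25 classes written before the data were examined. A name needed at least 3 markers with a log2 fold of at least 1.0 and a UMI in at least 10% of cells, and either a marker among the cluster's top 10 genes or at least 60% of the markers. A cluster whose top 10 genes held more markers of another class than of its best class was left unnamed. Alpha-beta T clusters of that kind were kept out of the CD8 and CD4 classes. Alpha-beta T clusters were split into CD8 and CD4 by coreceptor UMIs in at least 25% of cells and a ratio of 2. These thresholds, and the 4 versions of the naming rule of which the last was used, were set after the data were seen, following a first look with z-scores. Names carry "-like" since no protein was measured. Shares are of the cells analysed, with exact Clopper-Pearson 95% intervals.

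Within a class UMIs were summed per library and divided by the class total (CPM), and the log2 NAV/MOCK ratio was given an exact 95% interval conditional on the sum of both counts. With 0 counts in a library the ratio is a bound at a floor of 3 counts over the class. The genes named were 10 fixed CD8 genes, the 8 genes highest in each library in CD8 T-like cells and the 4 highest in each other class of at least 200 cells per library, ranked by the bound of the interval nearest to 0 among genes with at least 50 CPM and 50 UMIs, and up to 3 members of each list read in a class. Genes with mt-, Rpl, Rps, Gm, Rik or Hb symbols, antigen receptor segments, sex-linked markers and background list genes were left out of the ranking. Genes given for the library-wide shift were chosen after their values were seen. List medians used members with at least 20 UMIs over both libraries, with an interval from 1000 Poisson resamples and a percentile among 10000 random lists matched in 20 expression bins, and needed 3 members. T cell lists were read in T, NK and innate lymphoid classes, myeloid lists in monocyte, macrophage and dendritic classes, the immunosuppressive list in neutrophils, and the other lists in classes of at least 200 cells per library. CD8 T-like cells fell below that in MOCK, so in them only the lists of T cell cytotoxicity, exhaustion, memory and activation were fixed, and the lists of the interferon responses, MHC class I, COPI, protein folding, cGAS-STING, stress, glycolysis and cell cycle were added after the data were seen. For shares of cells with a UMI each cell was thinned to 1300 UMIs, from the 20th percentile of CD8 T-like depth in the shallower library, and shallower cells were left out.

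With 1 library per group no test between groups was made, and intervals and floors cover counting error only. Alternatives were a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial), doublets kept, Leiden resolution 2.0, libraries clustered separately, other denominators, median-of-ratios scaling, equal weight per cell, no minimum of UMIs for list members, unthinned shares and ratios minus the median ratio of the same gene over the other large classes. Alternatives chosen after seeing the data were the 3 earlier naming rules, list medians minus the other classes' ratios, list medians minus the median of the same decile of GC content, and removal of an interferon-led cluster.

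The ratios and list medians were tested on simulated data with known folds in CD8 T-like cells (3583 genes). Intervals lay beyond 0 in the right direction for 55.2% of genes set 1.5-fold apart, 83.6% at 2-fold and 100% at 4-fold, and held the true value for 96.3% of unchanged genes. Of lists left unchanged, 1% lay above percentile 97.5 and 3% below percentile 2.5. The simulated class sums were Poisson counts, as the intervals assume, and list members were random genes drawn independently. Spread between cells beyond counting error and shared regulation of list members were therefore not tested. Cells of unnamed clusters and removed doublets entered no class. The computations used Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.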

Results

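CD45+ cells, the leukocytes of a tissue, were profiled from mouse intrahepatic cholangiocarcinoma, a cancer of the bile ducts inside the liver, by single-cell RNA sequencing on the BD Rhapsody platform, which captures single cells in microwells with barcoded beads. Tumours were raised in C57BL/6 mice by hydrodynamic delivery, a rapid injection that brings plasmids into hepatocytes, of vectors for activated AKT and activated YAP. From day 7 the mice received either a mock treatment or NAV2729, an inhibitor of the activation of ARF GTPases, small proteins of which some recruit the COPI coat to Golgi membranes. The dose was 30 mg/kg every other day for 7 days. Each treatment gave 1 pooled library, called MOCK and NAV here. The series' design text gives 6 tumours per pool and its protocol gives 3 paired tumours, so the size of each pool is uncertain. The MOCK library held 45976676 UMIs in 10863 barcodes and the NAV library 31454031 UMIs in 10465 barcodes, with medians of 3840 and 2169 UMIs per barcode. After filtering and doublet removal 10078 MOCK and 9838 NAV cells were analysed. With 1 library per group no difference has a replicate check and none was tested. Intervals are 95% intervals that cover counting error only, and log2 ratios are NAV over MOCK.

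The first comparison asked whether the makeup of the leukocytes differed between the treatments, in a study directed at CD8+ T cells. CD8 T-like cells, the class of cytotoxic T lymphocytes, were 1.41% of the MOCK library (142 cells, 1.19 to 1.66%) and 2.63% of the NAV library (259 cells, 2.33 to 2.97%), a log2 ratio of 0.90 (0.60 to 1.21). A cluster led by CD8 T cell genes and removed as doublets went the other way, with 129 MOCK and 69 NAV barcodes. NK-like cells, innate cytotoxic lymphocytes, were 0.972% and 2.19% of cells (log2 ratio 1.17, 0.82 to 1.53), and CD4 T-like cells, the helper lineage, 0.963% and 1.68% (0.80, 0.43 to 1.18). The T, NK and innate lymphoid classes together were 5.48% of MOCK and 8.86% of NAV cells, a log2 ratio of 0.69 (0.54 to 0.85). The gd T/T17-like class, innate-like T cells that can secrete IL-17, was 1.35% and 1.14%, and the interval of its ratio held 0 (-0.25, -0.62 to 0.13). Treg-like cells (12 and 24) and ILC2-like cells (21 and 26) were too few for the direction to lie beyond counting error.

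Within the T, NK and innate lymphoid classes alone, without B-like cells, the CD8 T-like ratio was 0.21 (-0.09 to 0.51), which held 0. The higher CD8 T-like share of all cells thus went with a higher share of these classes together. On that denominator NK-like cells had a ratio of 0.47, CD4 T-like cells 0.11 and gd T/T17-like cells -0.94. The same cluster held the most CD8 T-like cells in both libraries, with 46 MOCK and 70 NAV cells. Among CD4 T-like cells a cluster led by Ccl5 and Pdcd1 held 4 MOCK and 34 NAV cells, and the larger clusters 59 and 91, and 34 and 40. T cells kept out of the CD8 and CD4 classes were 0.456% of MOCK and 0.722% of NAV cells.

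Myeloid cells were 79.5% of MOCK and 75.8% of NAV cells, with different classes within them. Kupffer-like cells, the resident macrophages of the liver, were 13.9% of MOCK and 3.70% of NAV cells (1405 and 364 cells, log2 ratio -1.91, -2.08 to -1.75). Macrophage-like cells were 25.1% and 15.2% (-0.72, -0.81 to -0.63), and classical monocyte-like cells, the blood precursors of many tissue macrophages, 12.3% and 9.08% (-0.44, -0.57 to -0.31). Higher in the NAV library were neutrophil-like cells (20.3% and 33.5%, 0.72, 0.64 to 0.80), nonclassical monocyte-like cells, which patrol vessels (2.83% and 5.92%, 1.06, 0.86 to 1.27), and plasmacytoid dendritic (pDC-like) cells, producers of type I interferon (0.447% and 1.42%, 1.67, 1.18 to 2.19). Of the conventional dendritic classes, which present antigen to T cells, cDC1-like cells had a ratio of 0.51 (0.06 to 0.97), cDC2-like cells 0.56 (0.36 to 0.76) and mature DC-like cells 1.07 (0.52 to 1.64). B-like cells were 10.1% and 11.9% (0.23, 0.11 to 0.35), and the cycling class 2.80% and 1.42%.

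Some classes were made of different clusters in the 2 libraries. Among neutrophil-like cells a cluster led by Retnlg and Stfa2l1 held the most in MOCK (952 MOCK and 532 NAV cells), and clusters led by Tnf and Cxcl3 (440 and 1353) and by Siglecf and Il1r2 (412 and 1245) held the most in NAV. A macrophage-like cluster led by Arg1 and Spp1 held 150 MOCK and 430 NAV cells, whereas the largest cluster, led by Mmp14 and Cxcl16, held 1029 and 530. The largest Kupffer-like cluster, led by Vcam1 and Mmp13, held 833 MOCK and 234 NAV cells and had 2 Kupffer markers among its top 10 genes. Kupffer-like clusters led by Cd5l and Clec4f (383 and 66 cells) and by Timd4 and C6 (189 and 64) had 7 and 8. Among classical monocyte-like cells the cluster led by Vcan and Ly6c2 held 394 and 442 cells, that led by Chil3 and Ccr2 633 and 436, and a cluster led by Saa3 held 214 and 15. Cells of unnamed clusters were 2.07% and 1.98%, and clusters removed as doublets held 4.77% and 4.01% of kept barcodes. All shares are of CD45-sorted cells, with median depths of 3698 and 1992 UMIs per cell. Within the larger classes the medians lay closer, at 1290 and 1169 in neutrophil-like, 4979 and 4515.5 in macrophage-like and 6684 and 5659.5 in Kupffer-like cells. The tables hold barcodes with at least 500 UMIs, so whether shallower cells were lost equally from both libraries could not be checked, which bears most on the shallow neutrophil-like and B-like classes. The classical monocyte-like ratio turned to 0.32 when the libraries were clustered separately, the neutrophil-like ratio was 0.32 at a finer clustering, and the Kupffer-like ratio ranged from -2.08 to -0.91 over 7 alternatives. The CD4 T-like ratio ranged from 0.39 to 1.49 over 7 alternatives and the nonclassical monocyte-like ratio from 1.14 to 1.97 over 6, and no MOCK cluster was named nonclassical monocyte-like when the libraries were clustered separately.

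**Figure D1:**
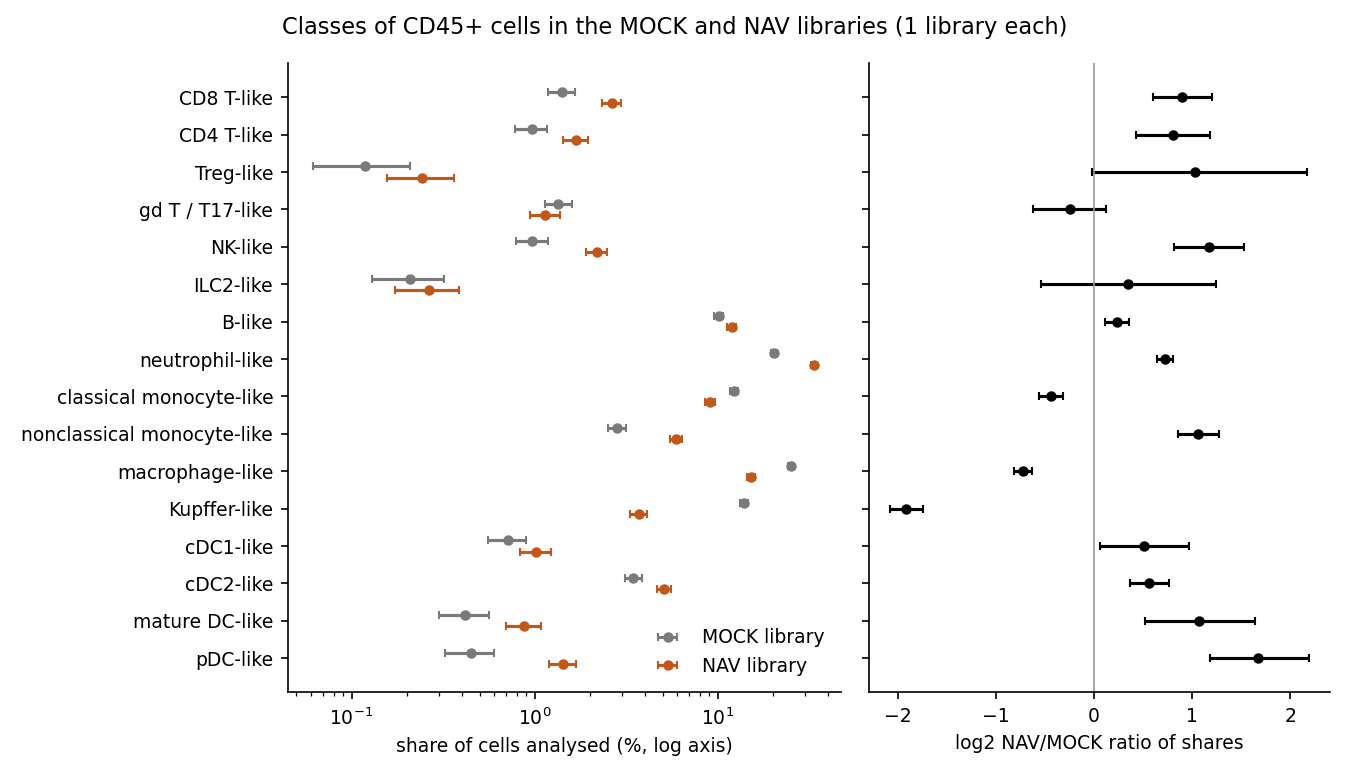
Share of each class among the cells analysed, on a log axis in percent, with exact 95% binomial intervals, for the MOCK and NAV libraries, and the log2 NAV/MOCK ratio of the shares with its 95% counting interval. Kupffer-like cells have the lowest ratio (-1.91) and pDC-like cells the highest (1.67), with CD8 T-like cells at 0.90.

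The next comparison was of expression within CD8 T-like cells, whose depth was alike in the libraries (medians of 2220.5 and 2243 UMIs). Of the genes fixed in advance, Ifng, the main effector cytokine of these cells, was higher in the NAV library (7 and 33 UMIs, log2 ratio 1.41, 0.21 to 2.83). These UMIs came from 5 of 142 MOCK and 15 of 259 NAV cells, and the interval counts each UMI as independent. Gzmb, the protease granzyme B, was lower (348 and 509 UMIs, or 1004 and 826 CPM, -0.28, -0.48 to -0.08). Intervals held 0 for Cd8a (-0.07), Prf1 (-0.13), Pdcd1 (0.16), Havcr2 (0.13), Lag3 (0.52), Tcf7 (-0.19) and Mki67 (-0.04). With doublets kept the Gzmb ratio was -0.06 and the Pdcd1 ratio 0.53. In GRCm38 the Gzmb gene (ENSMUSG00000015437) lies on chromosome 14 from 56258838 to 56262260, Ifng (ENSMUSG00000055170) on chromosome 10 from 118441046 to 118445892, and Pdcd1 (ENSMUSG00000026285) on chromosome 1 from 94038305 to 94052553. These and the other genes given with coordinates are protein-coding.

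The shares of CD8 T-like cells with a UMI were close in the libraries after thinning each cell to 1300 UMIs, which left out 26 MOCK and 36 NAV cells. Gzmb was detected in 36 of 116 MOCK cells and 64 of 223 NAV cells (28.7%), Pdcd1, an inhibitory receptor, in 40.5% and 40.8%, and Tcf7, a transcription factor of memory T cells, in 19.8% and 23.8%. Cd8a was detected in 59.5% and 58.3%, Prf1 in 7.76% and 7.17%, Ifng in 1.72% and 2.24%, Havcr2 in 6.90% and 5.38%, Lag3 in 2.59% and 3.59%, and Mki67 in 4.31% and 2.69%. Unthinned, Gzmb was detected in 35.9% and 34.7%, Pdcd1 in 43.0% and 45.6%, Tcf7 in 33.1% and 34.0%, Cd8a in 64.1% and 66.4%, Prf1 in 14.8% and 12.0%, Ifng in 3.52% and 5.79%, Havcr2 in 11.3% and 10.4%, Lag3 in 4.93% and 6.56%, and Mki67 in 6.34% and 6.18%. In B-like cells, with median depths of 1271.5 and 1369.5 UMIs, thinned shares were at most 0.421% for Gzmb, Pdcd1, Tcf7, Cd8a, Prf1, Ifng and Lag3, 2.32% and 1.96% for Havcr2, and 1.05% and 0.302% for Mki67. For each of these genes the binomial intervals of the libraries overlapped.

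**Figure D2:**
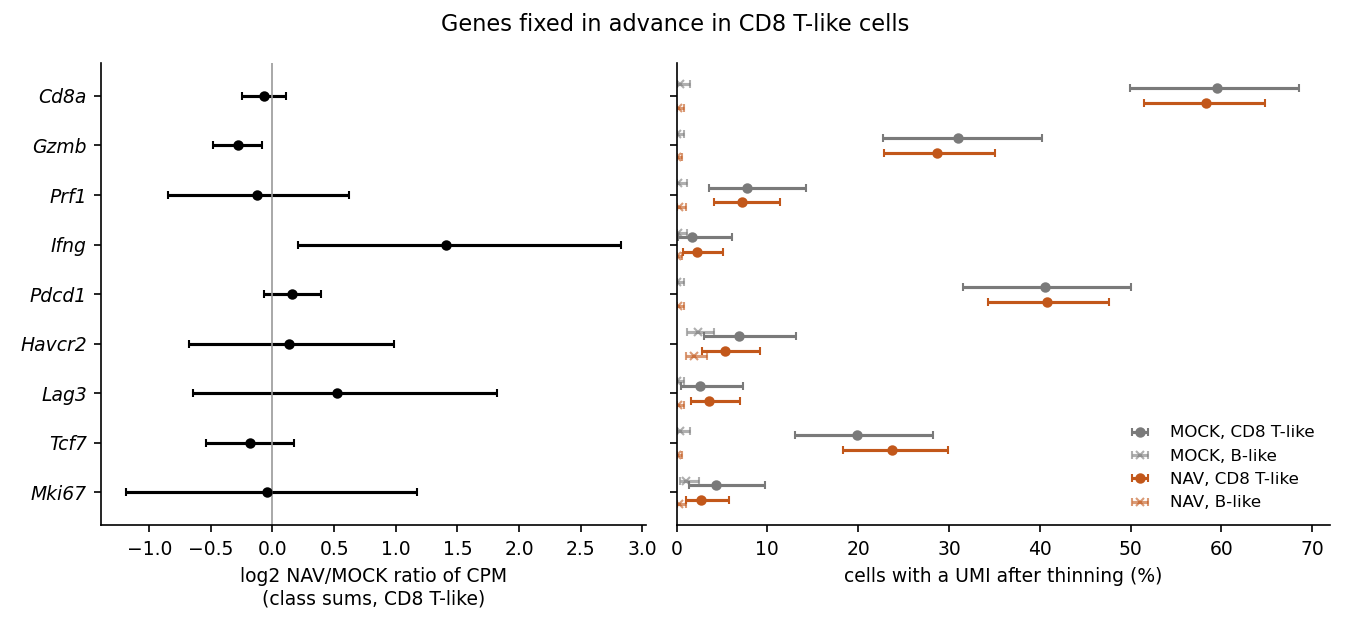
Log2 NAV/MOCK ratio of CPM for genes fixed in advance in CD8 T-like cells, with 95% counting intervals, and the percent of CD8 T-like and B-like cells with a UMI of each gene after thinning, with exact binomial intervals, per library. The interval of Ifng lies above 0 (0.21 to 2.83), from UMIs of 5 MOCK and 15 NAV cells, and that of Gzmb below 0 (-0.48 to -0.08).

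Among the gene groups fixed for T cells, that of exhaustion and inhibitory receptors, genes of chronically stimulated T cells, had a median log2 ratio of 0.21 (0.10 to 0.48) in CD8 T-like cells, at percentile 98.7 of 10000 random lists matched on expression, a percentile that describes these libraries. Of its 14 measured members 3 had intervals above 0 and 11 held 0. The 3 were Tox, a transcription factor of exhausted T cells (0.67, 0.33 to 1.02), Tnfrsf9, the costimulatory receptor 4-1BB (0.48, 0.21 to 0.75), and Entpd1, the ectonucleotidase CD39 (0.85, 0.10 to 1.65). Tox (ENSMUSG00000041272) lies on chromosome 4 from 6686353 to 6991557. The cytotoxic list had a median of 0.07 (-0.12 to 0.20), with 4 of 17 members above 0 and 3 below: the chemokine gene Ccl3 had a ratio of 1.23, Gzma, granzyme A, -0.44, and Lamp1, a lysosome membrane protein, -0.83. The naive and memory list had 0.04 (-0.15 to 0.26), with the homing regulator Klf2 at 0.43 and the IL-7 receptor gene Il7r at 0.85, and the activation list -0.08 (-0.35 to 0.12), with Cd28 at 0.73 and Cd69 at -0.47. With doublets kept the cytotoxic and exhaustion medians were 0.43 and 0.48, Entpd1 was at 0.24, Gzma at -0.0002 and Cd69 at -0.13, and the exhaustion median was 0.09 after subtracting the ratios of the same genes in the other large classes, which turned Tnfrsf9 to -0.26 and Cd28 to -1.02 and lowered Il7r to 0.28.

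The interferon-response and glycolysis lists had medians below 0 in CD8 T-like cells, in lists read in this class only after the data were seen, though most of their members did not lie below 0 beyond counting error. The type I interferon response list had a median of -0.83 (-1.14 to -0.31, percentile 0.015), with 6 of 13 members below 0 and 1 above. Isg15, an antiviral protein, was at 36 and 12 UMIs (-2.42, -3.49 to -1.44), Isg20, an antiviral exonuclease, at -1.28 and Ifi27l2a at -0.96. The interferon-gamma response list had -0.43 (-0.64 to -0.22, percentile 0.05), with 4 of 12 members below 0 and 8 that held 0, and the GTPase genes Irgm2 at -1.52, Ifi47 at -0.63 and Gbp7 at -0.57. The glycolysis list had -0.43 (-0.70 to -0.13, percentile 0.09), with Eno1 at -1.77, Gapdh at -0.91 and Pkm at -0.81 below 0 and the other 7 of 10 members holding 0. The medians were 0.10 for MHC class I presentation, -0.01 for the unfolded protein response, 0.05 for dissociation stress, -0.07 for the cell cycle and -0.07 for cGAS-STING, and all 5 intervals held 0. A T cell cluster led by cycling genes (20 MOCK and 28 NAV cells) was kept out of the CD8 T-like class. The cell cycle list and Mki67 were thus read without it. The type I interferon median was -0.33 with equal weight per cell, -0.47 with doublets kept and -0.53 (-1.06 to 0.0044) without an interferon-led cluster of 7 MOCK and 8 NAV cells. The interferon-gamma median was -0.11 with doublets kept and -0.30 with equal weight per cell, and Gbp7 was at -0.11 with doublets kept. After subtracting the other classes' ratios Isg15 was at -0.61, the interferon-gamma median at -0.70, the glycolysis median at -0.25, Gapdh at -0.24 and Eno1 at -0.53.

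The COPI coat and ARF list had a median of -0.03 (-0.21 to 0.12, percentile 31.2) in CD8 T-like cells, with 15 of 20 members holding 0. RNA of these genes does not measure whether the compound blocked the activation of ARF GTPases. Arf4, an ARF GTPase, had a ratio of 0.42, Kdelr2, a receptor that returns proteins to the endoplasmic reticulum, -1.29, and Arfgap2, which stimulates GTP hydrolysis by ARF1, -1.83. Arfgap2 was lower in every large class, and its CD8 T-like ratio was 0.18 after subtracting theirs. In the other classes of at least 200 cells the list's median was -0.03 in B-like, 0.20 in neutrophil-like, 0.10 in classical and -0.01 in nonclassical monocyte-like, 0.0039 in macrophage-like, -0.09 in Kupffer-like and 0.07 in cDC2-like cells. The neutrophil-like value was -0.12 under median-of-ratios scaling, and the classical monocyte-like value -0.01 minus the other classes' ratios.

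Among the genes ranked highest in the NAV library in CD8 T-like cells, by the bound of the interval nearest to 0, were Alcam, an adhesion molecule that binds CD6 (2.37, 1.15 to 3.87), the genes Zfp592 (1.75), Mrpl9, of the mitochondrial ribosome (1.52), Xbp1, a transcription factor of the unfolded protein response (1.42), Areg, the growth factor amphiregulin (1.40), Stk26, a kinase (1.24), and Hspa1a, a heat shock protein (1.01). Ranked highest in MOCK were Pld3 (-3.29), Cct7, a chaperonin subunit (-2.92), Emp3 (-2.80), Tnfrsf18, the costimulatory receptor GITR (-2.33), Fau, a ribosomal protein precursor (-2.27), Ppp1ca, a phosphatase subunit (-1.89), Prelid1 (-1.86) and Eno1, the glycolytic enolase (-1.77). Of these last 8 genes, 7 were also lower in the NAV library in all 7 large classes, against 1 of the 8 highest in NAV that was higher in all of them. With those classes' ratios subtracted, Alcam was at 2.29, Hspa1a at 0.035, Pld3 at -1.30, Emp3 at -1.74, Tnfrsf18 at -0.92, Prelid1 at -0.65, Cct7 at -0.54, Fau at 0.15 and Ppp1ca at 0.60. Fau (ENSMUSG00000038274) lies on chromosome 19 from 6057844 to 6059524.

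A set of genes was lower in the NAV library whatever the cell class. Of 7114 genes measured in all 7 large classes (B, neutrophil, both monocyte classes, macrophage, Kupffer and cDC2), 54 had a log2 ratio of -1.0 or lower with an interval below 0 in every class, and 0 were higher by as much. Among the 54 were Usf1 (median over classes -3.83), Ppp1ca (-2.49), Fau (-2.41), Cct7 (-2.38) and Ctsd, the lysosomal protease cathepsin D (-2.33), and 6 had Rps or Rpl symbols. Their last 500 transcript bases had a median GC content of 55.8%, against 42.8% for the genes measured, and 37 of the 54 lay in the highest decile of GC content. Genes in that decile had median ratios of -0.02 to -0.38 in 9 classes, below the median of the other deciles in each. Across genes, which are not independent replicates, log2 ratios correlated between classes with Pearson r of 0.22 to 0.71.

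**Figure D3:**
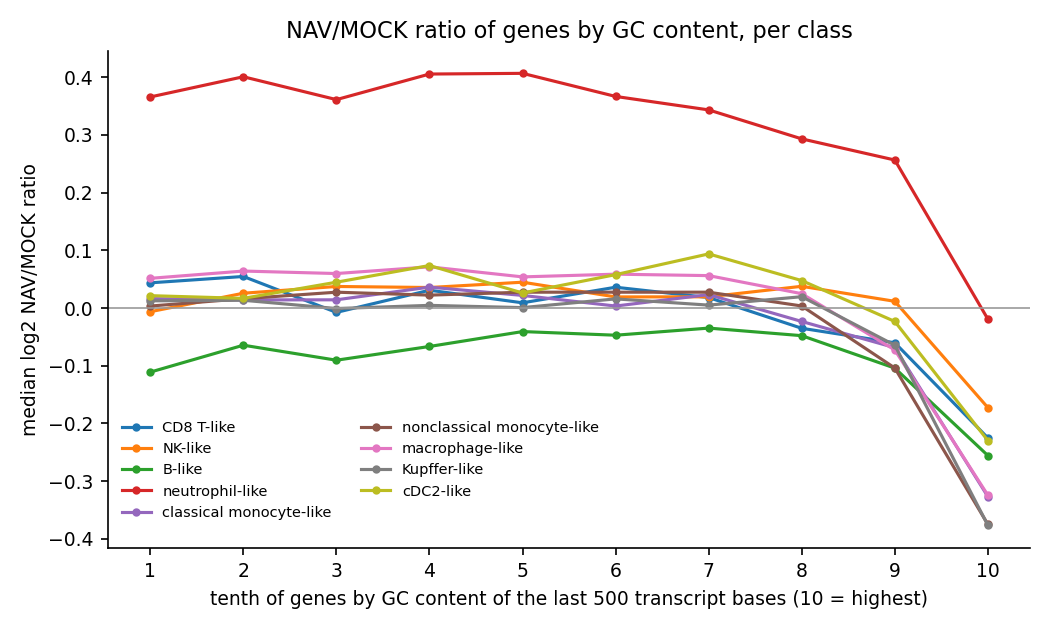
Median log2 NAV/MOCK ratio of the genes in each decile of GC content of the last 500 transcript bases (x axis, 10 is the highest), 1 line per class. In all 9 classes the highest decile lies below the others, at -0.23 in CD8 T-like and -0.38 in Kupffer-like cells.

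The other lymphoid classes were compared on the T cell lists. In CD4 T-like cells cytotoxic genes were higher in the NAV library, with a median of 1.503 (0.97 to 1.92), 8 of 14 members above 0 and none below. Ccl5, a chemokine of effector T cells, was at 114 and 1217 UMIs (2.60, 2.32 to 2.89), Ccl3 at 3 and 36 UMIs (2.77, 1.11 to 5.11), and Gzmk, granzyme K, at 0 and 25 UMIs, a log2 ratio of at least 2.24 at a floor of 3 counts, with an exact lower 95% limit of 1.84. The exhaustion list had 0.46 (0.19 to 0.76), with 2 of 10 members above 0, Tnfrsf9 at 1.36 and Havcr2, the receptor TIM-3, at 2.09, and the naive and memory list -0.21 (-0.38 to -0.06), with 2 of 11 below 0, among them Ccr7, a homing receptor for lymph nodes, at -0.62. The activation list had 0.09 and its interval held 0. The class held the cluster led by Ccl5 and Pdcd1 with its 4 MOCK and 34 NAV cells, and the lists were not read without it. With doublets kept the naive and memory median was 0.063 and Havcr2 was at 0.58.

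In NK-like cells the naive and memory list had a median of 0.67 (0.42 to 0.92, percentile 100), with 5 of 10 members above 0 and none below. Cd27, a receptor of less mature NK cells, had a ratio of 1.66 (0.97 to 2.41), Klf2 0.91 and Satb1, a chromatin organiser, 0.79. The cytotoxic list had 0.18 (-0.06 to 0.32), with Nkg7, a granule protein, at 0.53, Gzma at 0.46 and the chemokine gene Ccl4 lower, at 635 and 317 CPM. The exhaustion list had 0.09 and the activation list -0.15, both with intervals that held 0, and Icos, a costimulatory receptor, was at -1.29. The NK-like class held a cluster led by Gzma and Prf1 (74 MOCK and 176 NAV cells) and a deeper cluster led by Xcl1 and Gzmc (24 and 39). The lists were not read in these clusters apart. In gd T/T17-like cells the activation list had -0.56 (-0.65 to -0.23), with 5 of 9 members below 0 and 1 above. Il2ra, the IL-2 receptor, had -0.57 and Irf4 -1.26, and Nr4a2 and Id2 of the exhaustion list had -1.16 and -0.72. Cd27 in NK-like cells had a ratio of 0.60 after subtracting the other classes' ratios. With doublets kept Klf2 in NK-like cells was at 0.38 and the activation median in gd T/T17-like cells at -0.29.

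In Treg-like and ILC2-like cells the lists rest on few cells. In Treg-like cells the naive and memory list had -1.34 over 3 members and the exhaustion list 0.33 with an interval that held 0, as did 6 of its 7 members, the other being Pdcd1 at 1.28. In ILC2-like cells Nr4a2 had -1.45 and Tnfrsf18 -1.49, and the Tnfrsf18 value was -0.08 after subtracting the ratios of the large classes. The Treg-like naive and memory median was -0.52 with no minimum of UMIs.

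In cDC2-like cells, which formed 1 cluster, interferon-gamma response genes were higher in the NAV library, with a median of 1.06 (0.93 to 1.43, percentile 100), 11 of 16 members above 0 and none below. Cxcl9 and Cxcl10, chemokines that attract CXCR3+ T cells, were at 69 and 652 UMIs (2.84, 2.48 to 3.22) and at 147 and 652 UMIs (1.75, 1.48 to 2.01), and Gbp2, a guanylate-binding protein, was at 33 and 275 UMIs (2.65). Il12b, the p40 subunit of IL-12, which drives type 1 responses, was at 23 and 148 UMIs (2.28, 1.64 to 2.98). MHC class I presentation had 0.27, with the peptide transporter gene Tap1 at 0.82, and the unfolded protein response 0.30. The cell cycle list had 0.31, with 3 of 12 members above 0 and none below. It was read without the separate cycling class, which was 2.80% of MOCK and 1.42% of NAV cells. MHC class II presentation had 0.02 with an interval that held 0, and the inflammatory list -0.23, with Ccl5 at -0.93 and Ptgs2, the enzyme COX-2, at -0.58. After subtracting the other classes' ratios Cxcl9 was at 1.13, Tap1 at 0.18, and the medians were 0.76 for the interferon-gamma response, 0.15 for MHC class I and for the unfolded protein response, and -0.43 for MHC class II. The highest in MOCK were Mt2, a metallothionein (-3.26), Cyp4f18 (-3.19), Ppp1ca (-2.49) and Fau (-2.39), and the same subtraction left Mt2 at -1.60, Cyp4f18 at -0.83 and Fau at 0.032.

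The rarer dendritic classes were compared on the myeloid lists. In pDC-like cells MHC class II presentation had a median of 0.48 (0.30 to 0.70), and Ccl5 was at 0 and 29 UMIs, a log2 ratio of at least 1.62 at the floor, with an exact lower limit of 1.23. In mature DC-like cells the inflammatory list had -0.54 (-0.66 to -0.12), with 3 of 10 members below 0 and 1 above and the cytokine gene Il1b at -0.83, whereas Cd274, the checkpoint ligand PD-L1, had 0.67. That median was -0.08 with doublets kept. In cDC1-like cells MHC class II presentation had 0.19, and Ptgs2 was at 4 and 29 UMIs (2.42, 0.91 to 4.39). Minus the large classes' ratios the MHC class II medians were 0.265 in pDC-like and -0.13 in cDC1-like cells.

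In classical monocyte-like cells the interferon and antigen presentation lists had medians above 0. The type I interferon response list had a median of 0.60 (0.42 to 0.75, percentile 100), with 10 of 16 members above 0 and 2 below: Bst2, or tetherin, had a ratio of 0.91 and Zbp1, a nucleic acid sensor, 0.85, while Isg15 had -1.33. The interferon-gamma response list had 0.58 (0.32 to 0.77), with 6 of 13 members above 0 and 7 that held 0, Gbp2 at 1.32 and Ifi47 at 1.16. MHC class I presentation had 0.42, with 10 of 14 members above 0 and 2 below, Tap1 at 0.97 and the proteasome gene Psmb10 at -1.01. MHC class II presentation had 0.49, with 5 of 8 above 0 and 1 below, Cd74, the invariant chain, at 0.67 and H2-DMa at -1.82. The suppressive list had -0.31 (-0.46 to -0.23), with Arg1, arginase 1, at -1.05 and Trem2, a lipid receptor of macrophages, at -0.96. The inflammatory list had -0.30, with Nos2, the inducible nitric oxide synthase, at 89 and 3 UMIs (-4.18, -6.48 to -2.58). With the other classes' ratios subtracted, the type I interferon median was 0.51, but those of interferon-gamma, MHC class I and MHC class II were 0.11, 0.19 and 0.07, those of the suppressive and inflammatory lists -0.08 and -0.13, Isg15 was at 0.57 and Trem2 at 0.20. The cluster led by Saa3 held 214 MOCK and 15 NAV cells, so the class was not of 1 makeup.

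In nonclassical monocyte-like cells, which formed 1 cluster, Pecam1, an endothelial and leukocyte adhesion molecule, was at 7 and 167 UMIs (3.83, 2.76 to 5.17), Hmox1, the haem-degrading enzyme, at 74 and 501 UMIs (2.02, 1.66 to 2.39), and Hspa1b, a heat shock protein, at 126 and 884 UMIs (2.07). The inflammatory list had a median of -0.58 (-0.66 to -0.21), with Il1b at -0.78 and Il6 at -2.33, whereas the chemokine gene Ccl4 had 1.61. MHC class I presentation had 0.49, MHC class II presentation 0.57 and the interferon-gamma response 0.51, with 2 of 11 members above 0 and 2 below, and the type I list had -0.16 with an interval that held 0. After subtracting the other classes' ratios these medians were 0.18, 0.04 and -0.0535. With equal weight per cell the MHC class II median was 0.30. With doublets kept the inflammatory median was 0.043. A doublet cluster with markers of this class held 14 MOCK and 92 NAV cells.

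In macrophage-like cells type I interferon genes were lower in the NAV library, with a median of -0.45 (-0.64 to -0.30), below all 10000 random lists, and 12 of 17 members below 0 and none above. Isg15 had a ratio of -2.35, Irf7, the regulator of interferon genes, -1.37 and Ifit3 -1.31, and an interferon-led cluster held 110 MOCK and 31 NAV cells. MHC class II presentation had 0.53 (0.51 to 0.55), with H2-DMb1, a peptide-loading chaperone, at 0.91, Cd74 at 0.58 and H2-DMa at -1.72. The suppressive list had 0.17 (0.09 to 0.36), with Arg1 and Spp1, which lead the cluster that was larger in NAV, among its members. The inflammatory list had -0.24, with Ccl5 at -1.20 and Il1a at -0.60, and the stress list -0.26, with the immediate early gene Fosb at -1.37. After subtracting the other classes' ratios the MHC class II median was 0.03, Cd74 was at -0.0067, H2-DMa at -0.05, Isg15 at -0.61, Irf7 at -0.53, Fosb at -0.72, Il1a at -0.08, the inflammatory median was -0.09 and the suppressive median 0.50. Hepatocyte and biliary transcripts, traces of other cells in a CD45 sort, had medians of -1.17 over 4 members and -1.66 over 5.

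In Kupffer-like cells MHC class II presentation was higher in the NAV library, with a median of 0.97 (0.93 to 0.996), H2-Eb1 at 1.06 (1.01 to 1.12), Cd74 at 1.04 and H2-DMa at -1.50. The stress list had 0.38 (0.32 to 0.43), with Hspa1b at 1.80 (1.72 to 1.89) and Egr1 at 0.99, and Atf3, a stress transcription factor, and Gdf15, a stress cytokine, had 1.24 and 1.26. The interferon-gamma response list had 0.41, MHC class I presentation 0.33, and cGAS-STING 0.29 (0.02 to 0.40), with 1 of 5 members above 0. The type I interferon list had 0.18 with an interval that held 0 (-0.07 to 0.29). The glycolysis list had -0.33 (-0.48 to -0.25), with Eno1 at -1.87, and Il6 and the growth factor gene Vegfa had -1.41 and -0.63. After subtracting the other classes' ratios the medians of MHC class II, the interferon-gamma response and MHC class I were 0.42, 0.10 and -0.013, H2-DMa was at 0.27, Eno1 at -0.64, Atf3 at 0.78, Gdf15 at 0.80 and Il6 at -0.06.

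In neutrophil-like cells Hilpda, a lipid droplet protein induced by hypoxia, was at 1319 and 7787 UMIs (2.02, 1.94 to 2.11), Acot1, an acyl-CoA thioesterase, at 15 and 384 (4.14, 3.40 to 4.99), Cxcl3, a neutrophil chemokine, at 343 and 2281 (2.19), and Ptgs2 at 2081 and 6768 (1.16). Highest in MOCK were Cd177, a surface glycoprotein of neutrophils (-4.79), Fosl1 (-3.33), Hp, haptoglobin (-3.10) and Ifitm6 (-2.98). The immunosuppressive list had a median of 0.37 (0.06 to 0.46, percentile 97.0), with 8 of 17 members above 0 and 7 below, the unfolded protein response 0.50, and the type I interferon list -0.11 (-0.24 to -0.03), with Isg15 at -1.80 and Irf7 at -1.07. The median of all genes in this class was 0.34, and a median-of-ratios scaling lowered every ratio by 0.32, which left these 3 lists at 0.05, 0.18 and -0.43. Minus the other classes' ratios Isg15 was at 0.029 and Irf7 at -0.23, and a cluster led by Ifit3 and Ifit1 held 50 MOCK and 147 NAV cells. A cluster led by Ngp and Ly6g, with Cd177 among its leading genes, held 193 MOCK and 18 NAV cells.

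In B-like cells genes of the unfolded protein response, the chaperones and enzymes of protein folding in the endoplasmic reticulum, were higher in the NAV library, with a median of 0.70 (0.45 to 0.74, percentile 100), 11 of 15 members above 0 and none below. Xbp1 was at 79 and 236 UMIs (1.22, 0.85 to 1.61), Creld2 at 57 and 197 (1.43) and Hsp90b1 at 856 and 1809 (0.72). Txndc5, a disulfide isomerase, and Ly6c2 had ratios of 1.33 and 2.15. MHC class I presentation had 0.27, with H2-D1 at 0.43, and glycolysis -0.34, with Eno1 at -1.48, and Ciita, the activator of MHC class II genes, had -0.94. Highest in MOCK were Cyp4f18 (-2.28), Fau (-2.26), Ppp1ca (-2.19) and Hvcn1, a proton channel (-1.96). No cluster was named plasma-like, and with equal weight per cell the unfolded protein response median was 0.29, Xbp1 was at 0.52, Creld2 at 0.55, Txndc5 at 0.70 and Ly6c2 at 1.08. With doublets kept the median was 0.34. After subtracting the other classes' ratios the MHC class I median was -0.024, Eno1 was at -0.25, Hvcn1 at -0.46, Cyp4f18 at 0.27, Fau at 0.16 and Ppp1ca at 0.31.

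**Figure D4:**
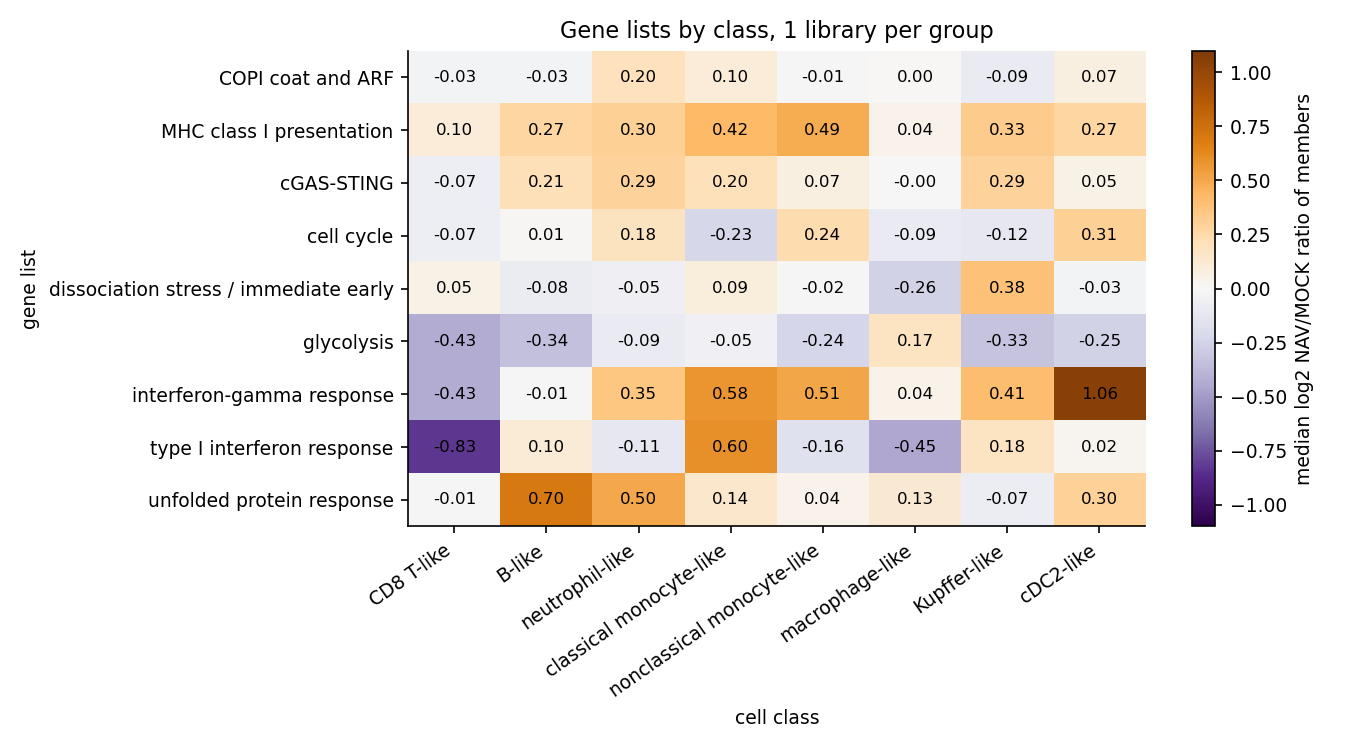
Median log2 NAV/MOCK ratio of the members of each gene list (rows) in each class (columns), as a colour scale, with 1 library per group. The interferon-gamma response list is highest in cDC2-like cells (1.06) and the type I interferon list lowest in CD8 T-like cells (-0.83) among the 8 classes shown.

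The hepatocyte, biliary and haemoglobin background lists had fewer than 3 measured members in most of the 8 classes read. The exceptions were the macrophage-like values above and a biliary median of 0.17 over 3 members in cDC2-like cells, whose interval held 0, and 0 haemoglobin genes were measured in the 8 classes read. Trf, transferrin, a hepatocyte list gene that myeloid cells also held, was at 7450 and 2217 UMIs in macrophage-like cells (-0.84) and at 8289 and 1568 in Kupffer-like cells (-0.23), and those ratios were -0.45 and 0.32 minus the other classes' ratios.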

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

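In this part the tests that subtract the other classes' ratios, leave out the interferon-led cluster or correct for GC content were chosen after the result was seen, as was the smallest size of 0.5 for a pair of opposite values.

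The type I interferon response list had opposite directions in a pair of classes. Its median log2 NAV/MOCK ratio was -0.83 in CD8 T-like cells and 0.60 in classical monocyte-like cells, and the difference between the classes was not tested. The CD8 T-like median was -0.33 with equal weight per cell and -0.47 with doublets kept. Macrophage-like (-0.45, -0.64 to -0.30) and neutrophil-like cells (-0.11, -0.24 to -0.03) also lay below 0, short of the smallest size. The intervals of the other large classes held 0. In CD8 T-like cells a shift shared by every large class does not account for the whole, since subtracting the ratios of the other classes left -0.57 (-0.83 to -0.18). Subtracting the median of the same decile of GC content left -0.74 (-1.01 to -0.26), but no decile lay below -0.23 in this class, so that correction could not have brought the interval to 0 and decides nothing about GC content. Without the interferon-led cluster the median was -0.53 (-1.06 to 0.0044), so whether that cluster carries the pattern cannot be told apart from a lower level in the other cells. A lower interferon response of CD8 T-like cells under NAV2729 may underlie it, but treatment and library are confounded with 1 library each.

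A cluster that the naming rule left unnamed was larger in the NAV library. Led by Cxcl9, Gbp2 and Iigp1, genes induced by interferon-gamma, it held 16 MOCK cells (0.159%) and 81 NAV cells (0.823%, 0.654 to 1.02%), and it entered no comparison between classes. Its best class was classical monocyte, with 10 markers up, but its top 10 genes held 1 endothelial marker and none of classical monocytes. It was therefore not counted as classical monocyte-like. No explanation of its larger share was tested.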

How the results depend on the processing

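In this part the alternatives chosen only after the results were seen were the 3 earlier naming rules, list medians minus the other classes' ratios, list medians minus the median of the same decile of GC content, and removal of the interferon-led cluster. All values are log2 NAV/MOCK ratios, and for each the cause was not tested. No paired analysis was possible because each group has 1 library.

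Of 14 class shares, 0 left their intervals with doublets kept and 0 of 9 with myeloid cells as the denominator. For CD8 T-like cells the doublet setting is a limited check. The removed doublet cluster led by CD8 T cell genes held 129 MOCK and 69 NAV barcodes. With doublets kept the class rose only from 142 to 177 MOCK and from 259 to 308 NAV cells, so not all of that cluster was counted in it. The ratio with the whole cluster counted as CD8 T-like was not computed. At Leiden resolution 2.0 the ratio was 0.39 for CD4 T-like, 1.23 for CD8 T-like, -0.28 for classical monocyte-like, 0.32 for neutrophil-like and 1.43 for nonclassical monocyte-like cells. Among T, NK and innate lymphoid classes it was 0.11 for CD4 T-like, 0.21 for CD8 T-like, 0.47 for NK-like and -0.94 for gd T/T17-like cells. With the libraries clustered separately it was 1.49 for CD4 T-like, -0.91 for Kupffer-like and 0.63 for neutrophil-like cells, and it reversed to 0.32 for classical monocyte-like cells. That setting gave no value for nonclassical monocyte-like cells, named in NAV (348 cells) but not in MOCK (0 cells). Under naming rule version 1 it was -0.62 for macrophage-like and 1.97 for nonclassical monocyte-like cells, and under versions 2 and 3 -0.15 for classical and 1.95 for nonclassical monocyte-like cells. Under the stricter filter it was 0.36 for B-like and 0.63 for neutrophil-like cells.

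The value of the CD8 T-like ratio stayed above 0 in all of these, but its interval held 0 among the T, NK and innate lymphoid classes. The 10 differences between the libraries in the share of CD8 T-like cells with a UMI stayed within their intervals unthinned, with doublets kept and under the stricter filter.

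Of 122 list medians, 106 stayed within their intervals with doublets kept, 114 with equal weight per cell, 108 under median-of-ratios scaling, 117 with no minimum of UMIs, 121 under the stricter filter, 116 after the correction for GC content and 76 minus the other classes' ratios, and 12 CD8 T-like medians without the interferon-led cluster. With doublets kept the cytotoxic and exhaustion medians in CD8 T-like cells were 0.43 and 0.48, and the inflammatory median in nonclassical monocyte-like cells (0.043) and the naive and memory median in CD4 T-like cells (0.063) reversed. With no minimum of UMIs the suppressive median in nonclassical monocyte-like cells reversed to 0.025. Under median-of-ratios scaling the COPI and MHC class I medians in neutrophil-like cells reversed to -0.12 and -0.016. Minus the other classes' ratios, medians in CD8 T-like cells were -0.40 for activation, 0.093 for exhaustion and -0.19 for naive and memory genes. From main values above 0 with intervals that held 0, MHC class I moved to -0.21 in CD8 T-like and -0.24 in macrophage-like cells. From such values the interferon-gamma response moved to -0.40 in macrophage-like and MHC class II to -0.43 in cDC2-like cells. Reversed under that setting were COPI (-0.014) and the unfolded protein response (-0.070) in classical monocyte-like cells, MHC class I in B-like (-0.024), Kupffer-like (-0.013) and neutrophil-like (-0.016) cells, MHC class II in cDC1-like (-0.13) and mature DC-like (-0.29) cells, glycolysis in nonclassical monocyte-like cells (0.021), the interferon-gamma response in neutrophil-like (-0.044) and nonclassical monocyte-like (-0.0535) cells, the suppressive list in Kupffer-like cells (0.095) and the unfolded protein response in macrophage-like cells (-0.032).

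Of the gene ratios, 343 stayed within their intervals with doublets kept, 335 with equal weight per cell, 349 under median-of-ratios scaling and 377 under the stricter filter. With equal weight per cell Cxcl10 in nonclassical monocyte-like cells (0.092) and Tnf in cDC1-like cells (-0.12) reversed. Minus the other classes' ratios 144 stayed within their intervals, 181 moved and 53 reversed. Cd8a and Tcf7 in CD8 T-like cells, whose main intervals held 0, moved to 0.82 and 0.64. In CD8 T-like cells those reversed were Arfgap2 (0.18), B2m (-0.11), Cd28 (-1.02), Fau (0.15), Ppp1ca (0.60), Psmb10 (0.73) and Tnfrsf9 (-0.26), in CD4 T-like cells Tcf7 (0.46), and in NK-like cells Tnfrsf18 (0.47). In B-like cells they were Cyp4f18 (0.27), Fau (0.16), Ppp1ca (0.31) and Psmb10 (0.0385). In Kupffer-like cells they were Arfgap2 (0.72), H2-DMa (0.27), Isg15 (0.48), Pdia6 (-0.24) and Trf (0.32), and in macrophage-like cells Arfgap2 (0.36), Cd74 (-0.0067), Eno1 (0.41), Tap1 (-0.16) and Tmem119 (0.23). In classical monocyte-like cells they were Arfgap2 (0.016), Eno1 (0.049), Isg15 (0.57), Pcna (-0.046), Pdia6 (-0.17), Psmb10 (0.51), Trem2 (0.20) and Trf (0.36). In nonclassical monocyte-like cells they were Calr (-0.058), Chil3 (0.34), Eno1 (0.077), Gapdh (0.16), Hsp90b1 (-0.13), Hspa5 (-0.0016), Ppp1ca (0.075) and Psmb10 (0.12). In neutrophil-like cells they were Arfgap2 (0.99), Gapdh (0.12), Hmgb2 (0.024), Hspa8 (0.11) and Isg15 (0.029). In dendritic cells they were Cd74 (-0.36) and H2-DMa (0.028) in cDC1-like, Fau (0.032), Gapdh (0.0020) and H2-DMb1 (-0.28) in cDC2-like, Cd74 (-0.28) and H2-DMa (0.31) in mature DC-like, and Cd74 (-0.095) and H2-Ab1 (-0.12) in pDC-like cells.

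Depth limits the rarer classes most: in simulated data 55.2% of CD8 T-like genes set 1.5-fold apart had an interval beyond 0, against 85.1% in macrophage-like cells.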

Other observations

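In this part the tests chosen only after the result was seen were the share of shifted genes with no shared word, the correction of shifted genes for GC content, and the CD8 T-like share without macrophage-like and Kupffer-like cells.

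Of 7114 genes, 54 had a log2 ratio of -1.0 or lower with an interval below 0 in all 7 large classes, and 0 were higher by as much. Against reads shared with other genes as the cause for every one of them, 77.8% had no 31-base word in another gene's transcript, close to 81.0% of all the genes. The median share of shared words was at percentile 50 of random gene sets, where nearly all sets have a median of 0, so that measure decides nothing. The GC content of the last 500 bases was at percentile 100 and transcript length at percentile 0, so a difference in library preparation that acts on GC-rich transcripts is a candidate explanation. Across 7110 genes the Spearman correlation of the ratio was -0.13 with GC content and -0.05 with transcript length. GC content and length correlated at -0.30, and the random sets were not matched on GC content. Length apart from GC content was thus not tested. Subtracting the median of their decile of GC content left the shifted genes at a median of -1.69 (quartiles -2.01 and -1.41), against -1.83 before, but they were picked for ratios of -1.0 or lower and no decile had a median over the classes below -0.20, so this decides nothing. An effect of NAV2729 on every cell class stays open, since treatment and library cannot be separated.

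The higher CD8 T-like share in the NAV library was weighed against how cells were named and what else was in the sort. Counting every kept barcode with a Cd8a or Cd8b1 UMI and a Cd3 or Trac UMI, with no clusters and no doublet removal, gave 193 MOCK and 289 NAV barcodes (1.79% and 2.77%), a log2 ratio of 0.63 (0.36 to 0.90), so naming and doublet removal do not account for all of it. Among cells that were neither macrophage-like nor Kupffer-like the ratio was 0.49 (0.19 to 0.80), so a lower share of those classes alone does not either. The T, NK and innate lymphoid classes together were also a higher share of NAV cells, and within them the ratio was 0.21, with an interval that held 0. B-like cells were not in that denominator, and their own share had a ratio of 0.23. The CD8 T-like ratio with B-like cells in the denominator was not computed. Whether the NAV tumours held more lymphocytes cannot be told from shares of a sort. Mononuclear phagocytes together, which include monocytes and dendritic cells, were 59.2% of MOCK and 42.3% of NAV cells. The CD8 T-like share without all of them was not computed. Differences between the pooled tumours stay open, as no tumour was measured alone.

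A cluster led by Prg4 and Alox15 met no naming rule and held 71 MOCK cells and 1 NAV cell (0.705% and 0.0102%). The other unnamed clusters held 43 and 59 cells (0.427% and 0.60%) and 79 and 54 cells (0.784% and 0.549%). A doublet cluster led by CD8 T cell genes held 129 MOCK and 69 NAV barcodes, and a T cell cluster led by cycling genes, kept out of the CD8 class, 20 and 28 cells.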
